A study of Mus musculus with 12 samples.

How the data were processed

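RNA from RAW264.7 macrophages was measured on 12 mouse 1-colour arrays (design 028005, 62976 spots), 3 for each of 4 groups, NS, HS, NS + LPS and HS + LPS. Per the file headers, the scanner values are intensity, linear and in arbitrary units, background subtracted and detrended within each array by Feature Extraction 10.7.3.1. The flags that mark outlier spots, saturation and signal above background are per the file headers of another kind than intensity, 0 or 1 for each spot. The deposited value table also holds linear intensity. Its median was 28.8 on every array and its values ranked as the scanner values did (Spearman 0.99996 or more), so it appears quantile normalized across arrays, though that step is inferred from the values and not stated. Groups were taken from the sample titles, and slide and scan day from the scanner files.

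Values were recomputed from the scanner files as log2 of the processed signal minus the array's 75th percentile over the 59305 non-control spots. Spots with an outlier flag were left out (10 probes that lost their value on any array were dropped), none was saturated, and repeated spots of a probe were averaged to 55681 probes. Of these, 32946 carried a gene symbol and 22735 did not, and 27509 were matched to a RefSeq accession. A probe was kept when well above background on all 3 arrays of at least 1 group, which 18715 probes with a symbol passed. The brightest probe stood for each of 13800 genes, 3935 of which had several probes. Some of these 3935 genes had probes called in both directions, 34 for salt without LPS and 155 for salt with LPS. The number was 423 for LPS without added salt, 503 for LPS with added salt and 48 for the interaction. For such genes the direction given rests on the brightest probe. Probe coordinates are on mm9. Among the 8299 unnamed probes that passed the filter, calls were made in a separate fit.

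Linear models were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, moderated variances), with contrasts for salt without LPS, salt with LPS, LPS without added salt, LPS with added salt and the interaction. Tests were limma's moderated tests, 2-sided, adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Gene lists, 28 of functions and 9 of markers of other cell types, were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 37 lists of a comparison, and again with an estimated correlation. A fold is given as at least a value when a group was not above background on any array. Correlations of effects are across genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15, and tables read with data.table (version 1.17.8) and blocks fitted with statmod 1.5.0.

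The groups, comparisons, lists, filter, tests and alternatives were chosen before the data were examined. Exceptions were cyclic loess normalization and the further tests named below as chosen after the data were seen. Genes named are, per comparison, from the 8 largest rises and 8 largest falls among called genes above background in both groups whose replicates do not overlap, which chance gives to 10% of genes at 3 arrays against 3. They also come from the 3 largest at-least folds in each direction, the up to 4 called members of each list with the largest differences, and index genes set in advance. Of 15 index genes 13 were measured, and Il10 and Arg1 did not pass the filter. The rule aimed at about 20 to 30 genes per comparison, which the text exceeds where lists are described, and results for some genes that the rule names are not reported here.

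The method was tested on simulated data with 200 of 13800 genes changed. It recovered 72 to 76% of log2 changes of 0.5 in the comparisons of a pair of groups and 57% in the interaction, and 81 to 90% of changes of 1, with 3 to 10 false calls. A simulated list of 20 genes shifted by 0.3 gave p = 2.83e-28 at the preset and 2.07e-06 at the estimated correlation, and 0 of 100 unshifted lists passed. The noise was drawn for each gene independently, so this result cannot speak for lists whose genes vary together. In the data the estimated correlation was 0.68 for ribosomal protein genes and 0.34 for osmolyte genes. The simulation also changed far fewer genes than were called in the data.

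The alternatives were normexp background correction (offset 50), quantile normalization, the deposited value table, no filter, genes above background on all 12 arrays, the mean of a gene's probes, an intensity trend in the variances, only the groups compared, array weights, blocks for replicate number and slide, the shared slide alone, an estimated correlation and leaving out each array. Blocks could not separate HS + LPS from its slide. Control spots were left out.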

Results

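RNA levels in RAW264.7 cells, a mouse macrophage line, were measured on 12 1-colour arrays. Per the labels, the cells received 40 mM added NaCl, with or without 10 ng/ml LPS, for 24 h. LPS (lipopolysaccharide) is a component of bacterial outer membranes that macrophages sense through the receptor TLR4. The labels name 4 groups, NS, HS, NS + LPS and HS + LPS, with 3 arrays each. They do not spell out the abbreviations, so HS was read as high salt, from the series title, and NS as the matching condition without added NaCl. The labels also do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

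The 75th percentile of the signal, a measure of each array's brightness, was 725 ± 74.0 in NS, 634 ± 21.5 in HS, 628 ± 6.84 in NS + LPS and 428 ± 15.3 in HS + LPS (mean ± SD, n = 3 arrays each). The share of probes well above background was 50.1 ± 0.60%, 48.8 ± 3.52%, 47.8 ± 2.49% and 44.2 ± 0.53% in the same order. Correlations across probes between replicates of a group lay between 0.996 and 0.999. The NS and HS arrays and NS + LPS replicates 1 and 2 shared a slide. NS + LPS replicate 3 was on another slide scanned on the same day, and the 3 HS + LPS arrays were on a slide of their own scanned on a later day. Every comparison that involves HS + LPS therefore cannot be told apart from slide and scan day, and no within-slide value exists for it. Of 13800 genes tested, the median standard error of a log2 difference was 0.066 in each comparison of a pair of groups and 0.093 in the interaction. The number of arrays limits the precision.

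**Figure D1:**
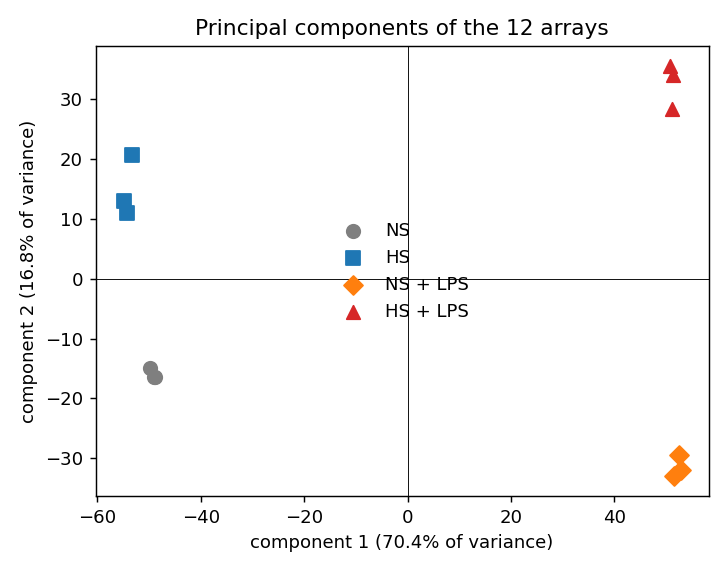
Scores of the 12 arrays on the first and second principal component of log2 signal, which hold 70.4% and 16.8% of the variance; each point is an array, coloured by group. The first component separates arrays with and without LPS.

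**Figure D2:**
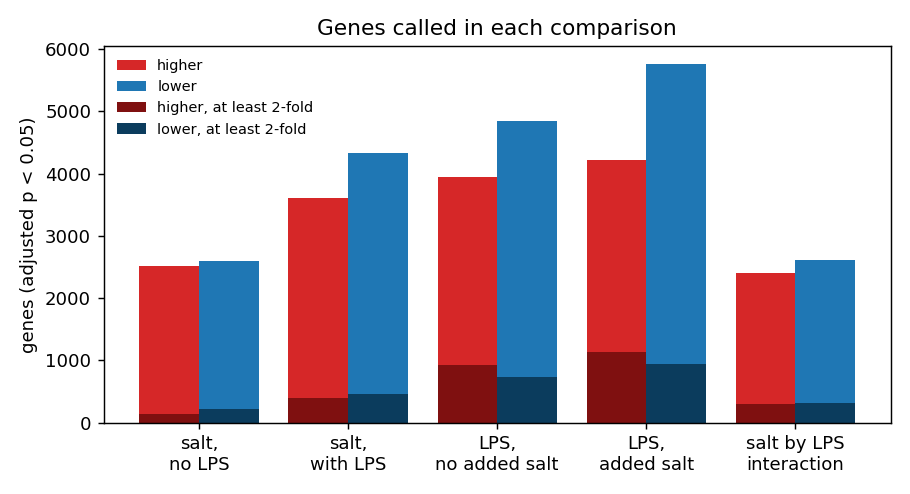
Number of genes called higher and lower (y axis) in each of the 5 comparisons (x axis), with those that changed at least 2-fold marked. Salt changed 5116 genes without LPS and 7933 with LPS, and LPS changed 8793 and 9974.

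The first comparison, HS against NS, asked which genes differ with added NaCl in resting macrophages. Genes that load cells with compatible osmolytes rose (n = 3 arrays per group here and below). Slc6a12, the betaine transporter, was 6.67-fold higher (log2 difference 2.74, SE 0.14; chromosome 6, 121315541 to 121315600, mm9 probe coordinates). Slc5a3, the myo-inositol transporter, was 5.89-fold higher (2.56, SE 0.12; chromosome 16, 92079366 to 92079425). Akr1b3, the aldose reductase that makes sorbitol, rose by 1.10 (SE 0.14), and Nfat5, the transcription factor that drives this program under high tonicity, by 0.84 (SE 0.060). The taurine transporter Slc6a6 rose by 0.17 (SE 0.053, adjusted p = 0.0267), a call lost with no filter on dim probes and without NS replicate 2 (0.16) or 3 (0.15) or HS replicate 2 (0.17) or 3 (0.16).

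Among genes well above background in both groups, the largest rise was that of Ambp, the precursor of the protease inhibitor bikunin, at 14.6-fold (3.87, SE 0.12, adjusted p = 2.24e-07; chromosome 4, 62804386 to 62804711). The sulfotransferase gene Chst1 rose by 3.37 (SE 0.34) and the ether lipid monooxygenase gene Agmo by 3.31 (SE 0.17). Of these genes, Pira2, which codes for an immunoglobulin-like receptor of myeloid cells, fell most, 7.21-fold (-2.85, SE 0.23). The G-protein regulator Rgs1 was 5.29-fold lower (-2.40, SE 0.097). For Slc6a12, Ambp, Chst1, Agmo, Pira2 and Rgs1 all 3 HS arrays lay on the same side of all 3 NS arrays. The rule that names the largest rises and falls required such separation in each comparison of a pair of groups, so it adds no support. Prima1, a membrane anchor of acetylcholinesterase, was at least 10.6-fold higher and the orphan receptor gene Gpr34 at least 5.94-fold lower, each well above background in 1 of the groups only. The monocyte attractant Ccl2 was 4.98-fold lower (-2.32, SE 0.14) and the scavenger receptor Cd36 4.06-fold lower (-2.02, SE 0.14).

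Of 13800 genes, 2519 were called higher and 2597 lower, and 134 and 224 of these changed at least 2-fold. Of the called genes 49.2% were higher, against 42.5% with quantile normalization and 39.5% with cyclic loess. With normexp background correction, 159 genes in all changed at least 2-fold against 358, and with genes well above background on every array 217 did. Within the slide that holds both groups, 4837 genes were called. The nitric oxide synthase gene Nos2 (0.16, adjusted p = 0.366), the cytokine Tnf (-0.061, adjusted p = 0.297) and the chemokine Cxcl10 (-0.065, adjusted p = 0.378) were not called. Il6 and Il1b were not well above background on any NS or HS array. Gapdh (0.13, adjusted p = 0.133; -0.024 with quantile normalization) and Actb (0.15, adjusted p = 0.0525), which serve as loading controls elsewhere, were not called.

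By gene list, 12 of 14 osmolyte and tonicity genes rose and none fell, also 12 and none when adjusted over the list alone (median 0.65; camera adjusted p = 5.32e-06, and adjusted p = 0.354 with an estimated correlation between genes). Interferon-stimulated genes, which carry the antiviral response, went the other way, with 32 of 40 lower and 1 higher (median -0.40, adjusted p = 7.58e-12, and adjusted p = 0.138 with an estimated correlation), or 32 and 3 adjusted over the list alone. Ifi204 fell by 1.20 (SE 0.074) and the nucleic acid sensor Zbp1 by 1.13 (SE 0.068). Of 21 antimicrobial effector genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.19, adjusted p = 0.00336, and adjusted p = 0.354 with an estimated correlation), among them Acod1, whose enzyme makes itaconate (-0.73, SE 0.053). Antigen presentation and co-stimulation genes fell in 11 of 18 and rose in 2 (12 and 2 adjusted over the list alone, median -0.28, adjusted p = 0.00138, and adjusted p = 0.354 with an estimated correlation), with the inhibitory ligand Cd274 at -1.06 and the peptide transporter Tap1 at -0.75.

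Genes of alternative activation, a state tied to tissue repair, fell in 7 of 11 and rose in none, the same adjusted over the list alone (median -0.68, adjusted p = 0.00111, and adjusted p = 0.183 with an estimated correlation). Besides Cd36 these included the scavenger receptor Stab1 (-1.31). The median was -0.374 with normexp correction, -0.397 without HS replicate 2 and -0.089 with no filter, and the call held. Macrophage identity and surface receptor genes fell in 13 of 26 and rose in 4 (13 and 6 adjusted over the list alone, median -0.19, adjusted p = 0.0245, and adjusted p = 0.385 with an estimated correlation), with the fungal sensor Clec7a at -1.49. That call also ended over genes well above background on all 12 arrays (adjusted p = 0.0609) and when only the groups compared were fitted (adjusted p = 0.0566), with a median of -0.097 in both. Autophagy and lysosome genes fell in 22 of 40 and rose in 5 (22 and 7 adjusted over the list alone, median -0.16, adjusted p = 0.0016, and adjusted p = 0.354 with an estimated correlation), for example the protease Ctsd (-0.61). Amino acid and integrated stress response genes fell in 20 of 29 and rose in 1 (20 and 2 adjusted over the list alone, median -0.24, adjusted p = 1.07e-05, and adjusted p = 0.354 with an estimated correlation). The stress factors Atf3 (-1.87, SE 0.13) and Trib3 (-1.78, SE 0.13) led that list.

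Heat shock genes rose in 8 of 14 and fell in 1 (9 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.00473, and adjusted p = 0.354 with an estimated correlation), with the chaperone Hsph1 at 0.42. Ribosome biogenesis genes rose in 18 of 26 and fell in 2 (19 and 2 adjusted over the list alone, median 0.21, adjusted p = 8.51e-05, and adjusted p = 0.354 with an estimated correlation), with the polymerase subunit Polr1b at 0.37. Ribosomal protein genes rose in 5 of 30 and fell in none (3 and none adjusted over the list alone, median 0.13, adjusted p = 0.00138, and adjusted p = 0.681 with an estimated correlation). For these the direction rested on the scaling, since the median was -0.0040 with quantile normalization (adjusted p = 0.473) and -0.0050 in the deposited value table (adjusted p = 0.477), and 0.057 with cyclic loess.

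The other 17 lists were not called (adjusted p from 0.0922 to 0.957). Of their 362 members, 71 rose and 75 fell, or 64 and 76 adjusted over the list alone. By list, 5 of 18 ion transporter genes rose and 2 fell. The counts were 4 higher and 5 lower of 19 inflammatory cytokines, led by the stress cytokine Gdf15 (-1.93, SE 0.082), 3 and 6 of 13 chemokines, and 5 and 6 of 20 NF-kB regulators. Osteoclast genes gave 2 and 7 of 13. In metabolism they were 4 and 1 of 38 for oxidative phosphorylation, 4 and 1 of 20 for glycolysis, 0 and 4 of 16 for HIF-1 and hypoxia, 5 and 0 of 22 for the TCA cycle, 6 and 1 of 23 for cholesterol synthesis, and 7 and 8 of 25 for lipid handling. The rest were 2 and 3 of 21 for the unfolded protein response, 7 and 6 of 26 for NRF2 targets, 7 and 1 of 34 for the cell cycle, 3 and 9 of 20 for cell cycle arrest and p53 targets, 3 and 5 of 13 for matrix genes, and 4 and 10 of 21 for immediate early genes. The cytokine list had a median of 0.078 and a mean of 0.043 while its test pointed down, and the median and mean also differed in sign for the NRF2 and matrix lists. The 9 lists of markers of other cell types, 29 genes measured, held 5 genes higher and 5 lower (4 and 4 adjusted over the list alone), with adjusted p from 0.195 to 0.823.

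**Figure D3:**
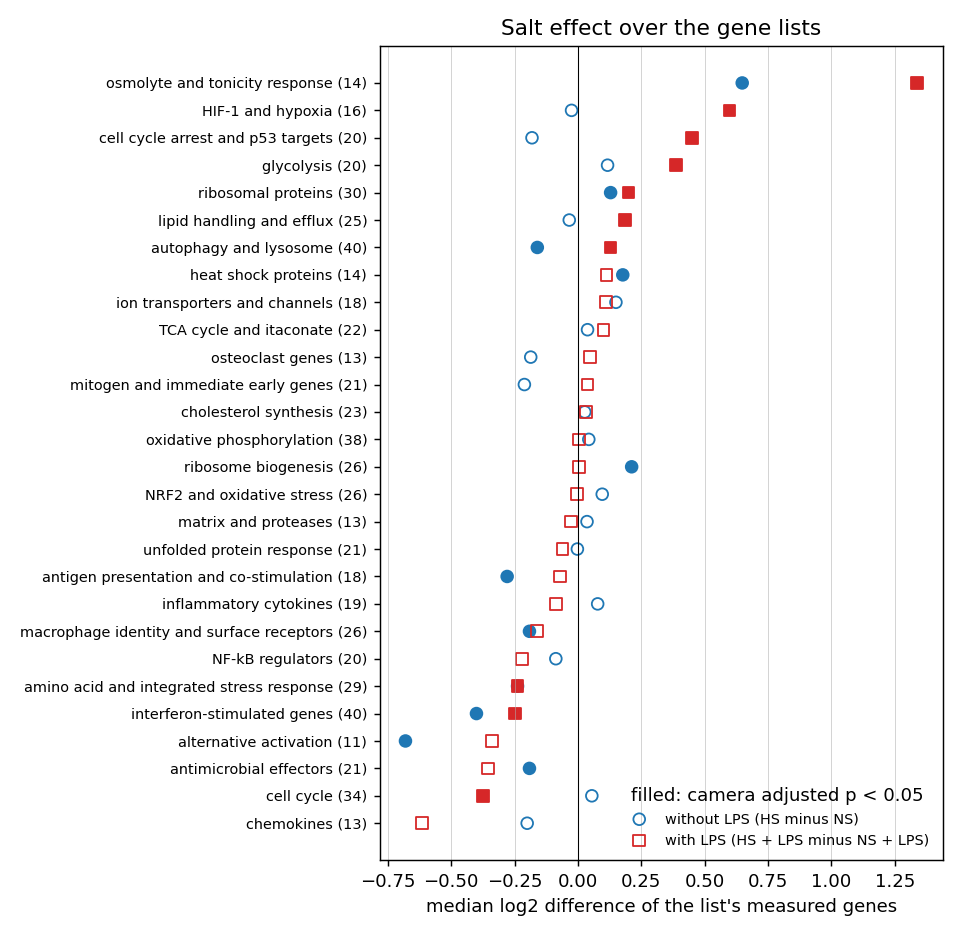
Median log2 salt effect of each gene list (x axis) without and with LPS; filled points passed camera at the preset correlation, open points did not. The osmolyte list had a median of 0.65 without LPS and 1.34 with LPS (interaction adjusted p = 0.0104, and 0.497 with an estimated correlation). The interferon-stimulated list had -0.40 and -0.25, a difference that was not called (interaction adjusted p = 0.0804).

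The second comparison, HS + LPS against NS + LPS, asked what added NaCl does to cells activated by LPS; slide and scan day differ between these groups. Ccl2, a monocyte attractant, was 28.5-fold lower (-4.83, SE 0.14; chromosome 11, 81850650 to 81850709) and Il6 11.4-fold lower (-3.51, SE 0.18; chromosome 5, 30346367 to 30346426). Ccl7, a related attractant, was at least 56.0-fold lower, being well above background in NS + LPS only. Il1b was 5.09-fold lower (-2.35, SE 0.084), Cxcl10 2.53-fold lower (-1.34, SE 0.054) and the siderophore-binding Lcn2 5.46-fold lower (-2.45, SE 0.092). Nos2, which makes nitric oxide, went up instead, 6.24-fold (2.64, SE 0.13; chromosome 11, 78773567 to 78773626), and Tnf by 0.20 (SE 0.043, adjusted p = 0.00279).

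The osmolyte genes named in the first comparison rose here too. Slc6a12 was 10.0-fold higher (3.32, SE 0.14) and Slc5a3 rose by 2.34 (SE 0.12). Akr1b3 rose by 2.33 (SE 0.14), Nfat5 by 0.90 (SE 0.060) and Slc6a6 by 0.64 (SE 0.053). Of the genes well above background in both groups, Rab15, a small GTPase of endosome recycling, rose most, 114-fold (6.84, SE 0.35). Others that rose were the sarcomere gene Myom1 (4.24, SE 0.16), the transcription repressor Gfi1 (4.06, SE 0.14) and the ephrin receptor Epha2 (3.62, SE 0.14). Clec7a was 9.62-fold lower (-3.27, SE 0.16) and Cd36 7.07-fold lower (-2.82, SE 0.14). The replicates of Rab15, Myom1, Gfi1, Epha2, Ccl2, Il6, Clec7a and Cd36 did not overlap between the groups.

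There were 3610 genes called higher and 4323 lower, 391 and 466 of them at least 2-fold. Of these calls 45.5% were higher, against 51.4% with cyclic loess. In all 857 genes changed at least 2-fold, against 364 with normexp correction and 419 over genes well above background on all 12 arrays. Gapdh (0.36) and Actb (0.19) were called higher, calls that ended with quantile normalization (0.081 for Gapdh and -0.047 for Actb) and in the deposited value table. Acod1 fell by 0.74 (SE 0.053).

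In the lists, 12 of 14 osmolyte genes rose and none fell, the same adjusted over the list alone (median 1.34, adjusted p = 3.91e-07, and adjusted p = 0.405 with an estimated correlation), with the chaperone Hspa4l at 2.19. Interferon-stimulated genes fell in 27 of 40 and rose in 5, the same adjusted over the list alone (median -0.25, adjusted p = 0.000286, and adjusted p = 0.405 with an estimated correlation), led by Rsad2 (-1.45, SE 0.035). Glycolysis genes rose in 18 of 20 and fell in none, the same adjusted over the list alone (median 0.39, adjusted p = 3.02e-07, and adjusted p = 0.265 with an estimated correlation). The phosphofructokinase gene Pfkm (1.05) and its activator Pfkfb3 (1.25) were among them. With quantile normalization the median was 0.253. HIF-1 and hypoxia genes rose in 14 of 16 and fell in none (15 and none adjusted over the list alone, median 0.60, adjusted p = 3.86e-06, and adjusted p = 0.405 with an estimated correlation), with the oxygen sensor Egln3 at 1.61 and the mTOR inhibitor Ddit4 at 1.59.

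Cell cycle genes fell in 25 of 34 and rose in 2 (27 and 2 adjusted over the list alone, median -0.37, adjusted p = 3.38e-05, and adjusted p = 0.464 with an estimated correlation), with the replication licensing gene Cdc6 at -0.93 and Cdk1 at -0.82. Amino acid and integrated stress response genes fell in 22 of 29 and rose in none (22 and 1 adjusted over the list alone, median -0.24, adjusted p = 0.000206, and adjusted p = 0.464 with an estimated correlation), with Trib3 at -1.19. Cell cycle arrest and p53 target genes rose in 12 of 20 and fell in 6 (12 and 7 adjusted over the list alone, median 0.45, adjusted p = 0.0359, and adjusted p = 0.404 with an estimated correlation), including Trp53inp1 (2.33) and Sesn1 (2.20). Lipid handling genes rose in 14 of 25 and fell in 6 (15 and 6 adjusted over the list alone, median 0.19, adjusted p = 0.0327, and adjusted p = 0.477 with an estimated correlation), with the efflux transporter Abcg1 at 1.80 and the lipase Lpl at -1.72. Autophagy and lysosome genes rose in 22 of 40 and fell in 9, the same adjusted over the list alone (median 0.13, adjusted p = 0.0496, and adjusted p = 0.477 with an estimated correlation), with Wipi1 at 1.26. The arrest and lipid calls also ended with normexp correction (adjusted p = 0.104 and 0.126), with only the groups compared (0.081 for both) and with cyclic loess (0.0751 for both). The autophagy call, just under the threshold, ended with most alternatives (adjusted p from 0.0521 to 0.365), among them the fits without NS + LPS replicate 2 (0.0708) or 3 (0.0613) or HS + LPS replicate 2 (0.0627) or 3 (0.0593). With normexp correction its median also fell, to 0.05. Ribosomal protein genes rose in 19 of 30 and fell in 1, the same adjusted over the list alone (median 0.20, adjusted p = 0.000286, and adjusted p = 0.562 with an estimated correlation). With quantile normalization their median was 0.0090 (adjusted p = 0.955), and with the mean of each gene's probes 0.132.

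Another 18 lists were not called (adjusted p from 0.0522 to 0.843). Among their 363 members 105 rose and 118 fell, or 229 in all adjusted over the list alone. The inflammatory cytokines split into 6 higher and 9 lower of 19, and the chemokines into 4 and 7 of 13. For immune functions the higher and lower counts were 5 and 11 of 20 for NF-kB regulators, 4 and 13 of 21 for antimicrobial effectors, 5 and 7 of 18 for antigen presentation, 1 and 5 of 11 for alternative activation and 7 and 13 of 26 for macrophage identity. Osteoclast genes gave 4 and 3 of 13, and ion transporters 8 and 3 of 18. For metabolism and stress they were 5 and 7 of 38 in oxidative phosphorylation, 10 and 1 of 22 in the TCA cycle, 11 and 2 of 23 in cholesterol synthesis, 5 and 8 of 21 in the unfolded protein response, 5 and 2 of 14 in heat shock and 11 and 7 of 26 among NRF2 targets. Ribosome biogenesis gave 3 and 8 of 26, matrix genes 5 and 5 of 13 and immediate early genes 6 and 7 of 21. The median and mean differed in sign for the oxidative phosphorylation, NRF2, ribosome biogenesis and matrix lists. The 29 marker genes of other cell types held 4 higher and 12 lower (4 and 13 adjusted over the list alone), with adjusted p from 0.0967 to 0.843.

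Across genes, the salt effects without and with LPS correlated at r = 0.468 and rho = 0.362 (r = 0.294 with no filter on dim probes and 0.545 with normexp correction); genes are not independent replicates. Salt raised 1436 genes in both settings against 659 expected if the calls were independent and lowered 1451 against 814 expected. It moved 297 and 378 genes in opposite directions against 789 and 679 expected.

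**Figure D4:**
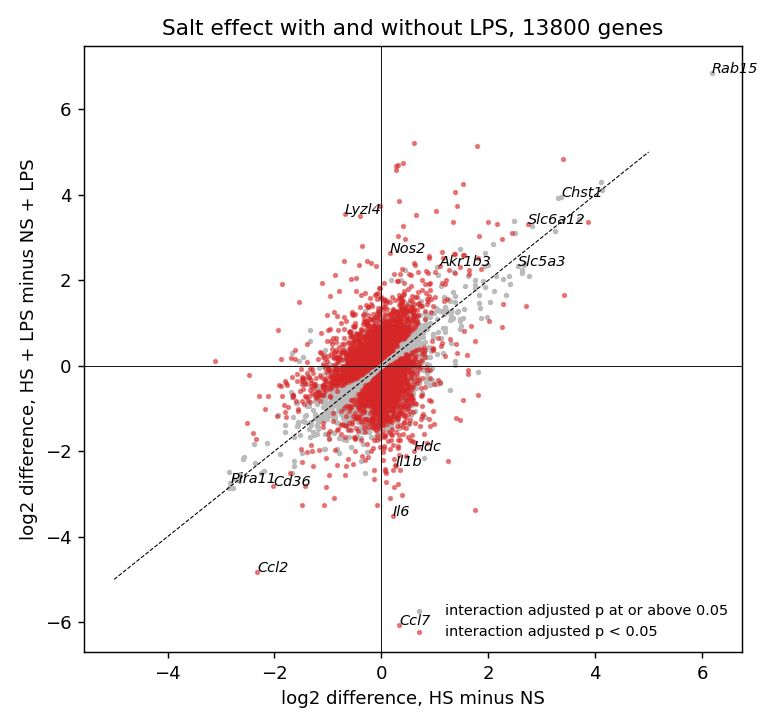
Log2 salt effect with LPS (y axis) against that without LPS (x axis), a point per gene; red points had a called salt by LPS interaction. Across 13800 genes r = 0.468, and 0.294 with no filter on dim probes.

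The third comparison, NS + LPS against NS, asked how these macrophages answered LPS without added salt. The attractant Ccl2 was 533-fold higher (log2 difference 9.06, SE 0.14), Lcn2 218-fold (7.77, SE 0.092), the antiviral Rsad2 172-fold (7.42, SE 0.035; chromosome 12, 27127859 to 27127918) and the prostaglandin synthase Ptgs2 136-fold (7.09, SE 0.080). The stefin gene Cstdc4 rose most among genes well above background in both groups, 586-fold (9.20, SE 0.13). Cytokine genes that were not well above background on any NS array became so with LPS, at least 401-fold higher for Csf3, 189-fold for Il6 and 73.0-fold for Il1b. Nos2 was 44.8-fold higher (5.48, SE 0.13), Acod1 48.9-fold (5.61, SE 0.053), Cxcl10 30.8-fold (4.94, SE 0.054) and Tnf 6.46-fold (2.69, SE 0.043).

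Of the genes well above background in both groups, Mical1, which oxidises actin, fell most, 20.4-fold (-4.35, SE 0.074). The surface glycoprotein gene Cd24a fell 19.1-fold (-4.26, SE 0.10), and Gas6, a ligand for clearance of dead cells, 11.9-fold (-3.57, SE 0.12). The sialyltransferase gene St6gal1 was at least 48.3-fold lower. For Ccl2, Lcn2, Rsad2, Ptgs2, Cstdc4, Mical1, Cd24a and Gas6 no replicate overlapped the other group. Among osmolyte genes, Nfat5 rose by 0.33 (SE 0.060), Slc5a3 fell by 0.39 (SE 0.12; the call ended without NS replicate 1, at -0.30), Slc6a6 fell by 0.75 (SE 0.053), and Akr1b3 (0.14, adjusted p = 0.394) and Slc6a12 (0.28, adjusted p = 0.101) were not called. Gapdh (0.19) and Actb (0.22) were called higher, Gapdh not with quantile normalization, within the shared slide, or without NS replicate 3 (0.12) or NS + LPS replicate 3 (0.15).

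LPS raised 3942 genes and lowered 4851, with 923 and 731 at least 2-fold. Of these calls 44.8% were higher, against 50.4% with cyclic loess. Without the filter on dim probes 5990 genes were called higher. Within the slide that holds NS and NS + LPS replicates 1 and 2, 8318 genes were called.

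Of 40 interferon-stimulated genes 39 rose and none fell (median 3.92, adjusted p = 2.12e-26), with Ifit3 at 7.03 and Zbp1 at 6.84. Inflammatory cytokines rose in 17 of 19 and fell in 2 (median 2.43, adjusted p = 6.99e-08), and chemokines rose in 9 of 13 and fell in 1 (median 3.34, adjusted p = 3.75e-05), with Ccl5 at 6.22. Matrix and protease genes rose in 10 of 13 and fell in 2 (median 1.42, adjusted p = 0.000288), including osteopontin, Spp1 (3.54). Immediate early genes rose in 17 of 21 and fell in 2 (median 1.19, adjusted p = 2.51e-06), with Egr1 at 2.70. These 5 calls held with an estimated correlation, at adjusted p = 0.00573 for the interferon and cytokine lists, 0.017 for chemokines, 0.0251 for matrix and 0.0472 for immediate early genes. With no filter the median was 1.39 for chemokines and 0.731 for matrix genes. For these and the next 7 lists, the counts were the same adjusted over the list alone.

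Regulators of NF-kB rose in 14 of 20 and fell in 3 (median 0.59, adjusted p = 0.000416, and adjusted p = 0.104 with an estimated correlation), with Socs3 at 3.30. Antimicrobial effectors rose in 15 of 21 and fell in 2 (median 1.33, adjusted p = 1.97e-05, and adjusted p = 0.0593 with an estimated correlation), with a median of 0.799 after normexp correction. Antigen presentation genes rose in 12 of 18 and fell in 5 (median 1.01, adjusted p = 0.00377, and adjusted p = 0.505 with an estimated correlation), with Tap1 at 2.31. Amino acid and integrated stress response genes rose in 24 of 29 and fell in 1 (median 0.43, adjusted p = 2.51e-06, and adjusted p = 0.205 with an estimated correlation), with Ddit3 at 2.25. The unfolded protein response rose in 16 of 21 and fell in 4 (median 0.37, adjusted p = 0.00577, and adjusted p = 0.544 with an estimated correlation), with Dnajb9 at 1.69. Cell cycle genes fell in 24 of 34 and rose in 4 (median -0.42, adjusted p = 0.00153, and adjusted p = 0.697 with an estimated correlation), with Ccna2 at -1.08. Oxidative phosphorylation genes fell in 25 of 38 and rose in 1, Cycs (median -0.22, adjusted p = 0.00827, and adjusted p = 0.722 with an estimated correlation), with Atp5a1 at -0.48.

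Not called were 16 lists (adjusted p from 0.0775 to 0.998), with 111 of 344 members higher and 117 lower, or 110 and 119 adjusted over the list alone. Higher and lower counts were 7 and 4 of 14 osmolyte genes, 4 and 6 of 18 ion transporters, 2 and 5 of 11 alternative activation genes, 13 and 11 of 26 identity genes and 6 and 3 of 13 osteoclast genes. Autophagy genes gave 18 and 15 of 40, with Wipi2 at 1.20. It turned to -0.51 when only the shared slide was fitted, where the brightest probe was chosen anew. Glycolysis genes split into 9 and 4 of 20, HIF-1 genes into 4 and 6 of 16, TCA cycle genes into 1 and 11 of 22, cholesterol synthesis into 5 and 8 of 23 and lipid handling into 7 and 17 of 25. Heat shock genes gave 5 and 3 of 14, with Dnaja1 at 0.47, which became -0.23 with the mean of its probes. NRF2 targets, cell cycle arrest and p53 targets and ribosome biogenesis gave 12 and 8 of 26, 10 and 7 of 20, and 7 and 9 of 26, and 1 of 30 ribosomal protein genes rose. The median and mean differed in sign for the identity, HIF-1, lipid and ribosome biogenesis lists, and the ion transporter test pointed up while its median and mean were below 0. In the marker lists 7 of 29 genes rose and 3 fell, the same adjusted over the list alone, with adjusted p from 0.0616 to 0.772.

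The fourth comparison, HS + LPS against HS, asked the same of LPS with salt present, again across slides and scan days. Nos2 rose most among genes well above background in both groups, 250-fold (7.96, SE 0.13). Zbp1 was 211-fold higher (7.72, SE 0.068), and the interferon regulator Irf7 (6.82, SE 0.099), the DNA-binding Ifi202b (7.42, SE 0.076) and Ptgs2 (7.35, SE 0.080) rose as well. The neutrophil attractant Cxcl2 was at least 918-fold higher and Csf3 at least 477-fold, while Il6 was at least 15.7-fold and Il1b at least 13.5-fold higher. Acod1 was 48.5-fold higher, Cxcl10 rose by 3.67 and Tnf by 2.95. St6gal1 was 18.6-fold lower (-4.22, SE 0.18), the inhibitory receptor gene Cd101 fell by 3.77 (SE 0.061) and the kynurenine enzyme gene Kmo fell by 3.03 (SE 0.061). For Nos2, Zbp1, Irf7, Ifi202b, Ptgs2, St6gal1, Cd101 and Kmo no replicate overlapped the other group. Akr1b3 rose by 1.37 (SE 0.14), Slc6a12 by 0.86 (SE 0.14) and Nfat5 by 0.39 (SE 0.060), while Slc5a3 fell by 0.61 (SE 0.12) and Slc6a6 fell by 0.28 (SE 0.053).

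Here 4212 genes were called higher and 5762 lower, 1127 and 944 at least 2-fold (2071 in all, against 1278 with normexp correction). The median over all genes was -0.11, and changes here are to be read against that shift. With cyclic loess normalization, chosen after the data were seen, the median was 0.033 and 54.5% of called genes were higher against 42.2%. Gapdh (0.42) and Actb (0.26) were called higher, Actb not with quantile normalization or in the value table.

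With LPS in salt, 39 of 40 interferon-stimulated genes rose and 1 fell (median 4.15, adjusted p = 2.63e-24), 16 of 19 cytokines rose and 1 fell (median 2.06, adjusted p = 3.41e-08), and 9 of 13 chemokines rose and 1 fell (median 1.83, adjusted p = 9.74e-05), with Ccl2 at 6.54. Matrix genes rose in 9 of 13 and fell in 1 (median 1.31, adjusted p = 7.42e-05), with Spp1 at 3.57. Immediate early genes rose in 18 of 21 and fell in none (median 1.38, adjusted p = 3.41e-08). Osteoclast genes, several of which macrophages share, rose in 11 of 13 and fell in 1 (median 0.88, adjusted p = 0.000379), among them Acp5 (1.26) and the collagenase Ctsk (1.22). Cell cycle arrest and p53 target genes rose in 13 of 20 and fell in 4 (median 0.41, adjusted p = 0.00341), with the cycle inhibitor Cdkn1a at 1.90. These 7 calls held with an estimated correlation, from adjusted p = 0.00725 for cytokines to 0.0451 for arrest and p53 targets. With no filter the medians of chemokine, matrix and osteoclast genes were 0.451, 0.266 and 0.361, and the chemokine median was 3.67 when only the groups compared were fitted. Adjusted over the list alone, the counts of all 19 called lists were the same, except that HIF-1 had 14 and 1.

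The remaining 12 calls ended with an estimated correlation. NF-kB regulators rose in 16 of 20 and fell in 2 (median 0.64, adjusted p = 6.17e-05) and antimicrobial effectors rose in 15 of 21 and fell in 4 (median 0.92, adjusted p = 6.08e-05), both with adjusted p = 0.0551 with an estimated correlation. Over genes well above background on all 12 arrays the antimicrobial median was 1.41. Antigen presentation genes rose in 14 of 18 and fell in 2 (median 1.18, adjusted p = 4.31e-05, and adjusted p = 0.206 with an estimated correlation). Glycolysis genes rose in 16 of 20 and fell in 3 (median 0.48, adjusted p = 0.000107, and adjusted p = 0.122 with an estimated correlation), with Hk3 at 1.78 and a median of 0.293 with quantile normalization. HIF-1 genes rose in 14 of 16 and fell in none (median 0.72, adjusted p = 6.17e-05), with Vegfa at 1.74, and amino acid and integrated stress response genes rose in 20 of 29 and fell in 3 (median 0.51, adjusted p = 3.61e-05). Both gave adjusted p = 0.218 with an estimated correlation. Autophagy genes rose in 26 of 40 and fell in 11 (median 0.27, adjusted p = 0.00311), with the cargo receptor Sqstm1 at 2.13, and cell cycle genes fell in 30 of 34 and rose in 2 (median -0.81, adjusted p = 1.13e-06), with Mki67 at -1.55. Both gave adjusted p = 0.275 with an estimated correlation. Osmolyte genes rose in 8 of 14 and fell in 2 (median 0.55, adjusted p = 0.0176, and adjusted p = 0.536 with an estimated correlation), with Aqp1, a water channel, at 2.55; cyclic loess gave adjusted p = 0.0630. Oxidative phosphorylation genes fell in 26 of 38 and rose in 2 (median -0.19, adjusted p = 0.010, and adjusted p = 0.754 with an estimated correlation). The unfolded protein response rose in 14 of 21 and fell in 5 (median 0.24, adjusted p = 0.0355, and adjusted p = 0.578 with an estimated correlation), a call that also ended with normexp correction (adjusted p = 0.145), quantile normalization (0.0504), the value table (0.0501), cyclic loess (0.079) and without HS replicate 1 (0.0611). Ribosome biogenesis genes fell in 19 of 26 and rose in 3 (median -0.27, adjusted p = 0.0350, and adjusted p = 0.639 with an estimated correlation), with Nop58 at -0.73 and a median of -0.439 with the mean of each gene's probes. Without HS replicate 3 that list gave adjusted p = 0.0620.

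The 9 uncalled lists (adjusted p from 0.109 to 0.897) held 66 higher and 68 lower of 195 genes, or 65 and 67 adjusted over the list alone. Higher and lower counts were 6 and 8 of 18 ion transporters, 3 and 4 of 11 alternative activation genes, 8 and 12 of 26 identity genes, 5 and 8 of 22 TCA cycle genes and 7 and 8 of 23 cholesterol synthesis genes. Lipid handling gave 7 and 13 of 25, heat shock 6 and 5 of 14, NRF2 targets 12 and 8 of 26, with Hmox1 at 3.24, and ribosomal proteins 12 and 2 of 30. For alternative activation and lipid handling the median and mean differed in sign, and the ion transporter test pointed up against a median and mean below 0. The marker lists gave 6 higher and 12 lower of 29, the same adjusted over the list alone, with adjusted p from 0.326 to 0.896.

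The LPS effects without and with salt correlated across genes at r = 0.844 and rho = 0.732. LPS raised 3103 genes in both against 1203 expected by independence and lowered 3865 against 2025, and it moved 182 and 226 in opposite directions against 1646 and 1481.

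**Figure D5:**
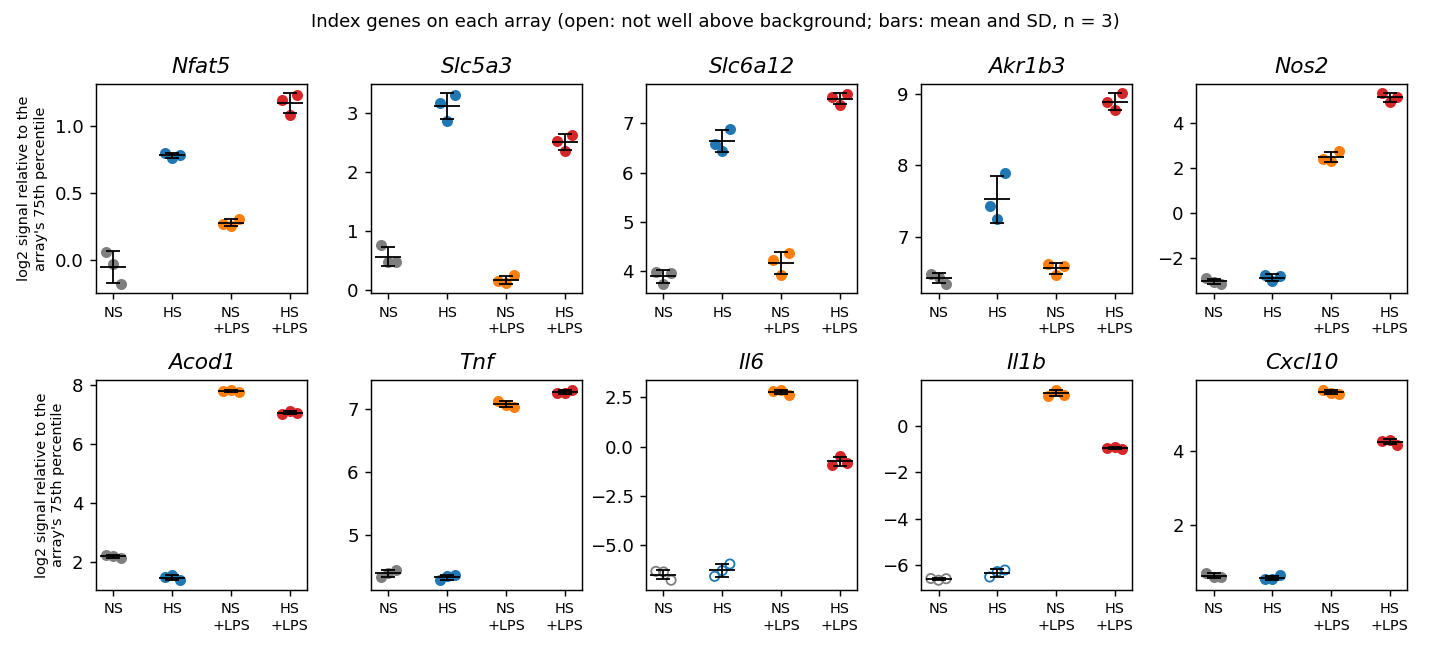
Log2 signal relative to the array's 75th percentile of 10 index genes on each array (y axis) in the 4 groups (x axis), with mean and SD; open points are arrays where the probe was not well above background. Nos2 was 6.24-fold higher and Il6 11.4-fold lower in HS + LPS than in NS + LPS.

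The last comparison, the salt by LPS interaction, asked whether the salt effect differed with LPS, and it too includes the HS + LPS slide. The salt effect on Nos2 was higher with LPS by 2.48 (SE 0.19, adjusted p = 1.53e-05). It was lower with LPS for Ccl2 (-2.52, SE 0.20), Lcn2 (-2.32, SE 0.13) and Cxcl10 (-1.28, SE 0.076). Il6 (-3.72) and Il1b (-2.62) were called too, but those values rest on groups without LPS that were not well above background. Akr1b3 (1.23, SE 0.19), Slc6a6 (0.47, SE 0.074) and Tnf (0.26, SE 0.061) had a higher salt effect with LPS. Nfat5 (0.061, adjusted p = 0.604), Slc5a3 (-0.22, adjusted p = 0.339) and Acod1 (-0.012, adjusted p = 0.911) were not called, nor were Gapdh (0.23, adjusted p = 0.0628) and Actb (0.042, adjusted p = 0.687). Slc6a12 was called at 0.59 (adjusted p = 0.0369), a call lost with array quality weights, with no filter on dim probes, and without each array but NS replicate 2, HS replicate 3, NS + LPS replicate 3 and HS + LPS replicate 2 (values from 0.46 to 0.61).

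Among genes well above background on all 12 arrays, the largest interaction was that of Lyzl4 (4.24, SE 0.17; chromosome 9, 121486967 to 121487026). Other large ones were those of Gdf15 (2.78, SE 0.12), Myom1 (2.72, SE 0.23), Gfi1 (2.69, SE 0.20) and Epha2 (2.60, SE 0.19), and, downward, the histamine-making enzyme gene Hdc (-2.61, SE 0.10) and Clec7a (-1.78, SE 0.23). The flippase gene Atp9a (2.99, SE 0.16) lost its call with the mean of its probes. In all 2407 genes were called higher and 2606 lower, 294 and 321 at least 2-fold, and these 615 became 226 with normexp correction and 294 over genes well above background on all arrays. Of the called genes, 48.0% were higher, against 58.3% in the value table and with quantile normalization and 61.3% with cyclic loess. Of the 5013, 2564 had a salt effect called only with LPS, 815 only without, 830 in the same direction in both, 675 in opposite directions and 129 in neither.

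HIF-1 and hypoxia genes had a higher salt effect with LPS in 13 of 16 and a lower effect in none (15 and none adjusted over the list alone, median 0.80, adjusted p = 2.93e-08, and adjusted p = 0.165 with an estimated correlation), with Bnip3 at 1.72 and Ddit4 at 1.61. Autophagy and lysosome genes did so in 22 of 40 against 1 (23 and 1 adjusted over the list alone, median 0.26, adjusted p = 3.51e-06, and adjusted p = 0.165 with an estimated correlation), with Wipi1 at 1.31. Osteoclast genes were higher in 7 of 13 and lower in 1 (7 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0324, and adjusted p = 0.165 with an estimated correlation), with Acp5 at 1.77. That call ended with normexp correction (adjusted p = 0.118), with cyclic loess (0.0604, where the median was 0.404) and without NS replicate 1 (0.0985), HS replicate 3 (0.0624) or NS + LPS replicate 3 (0.0679). With no filter its median was 0.109. The mast cell list, Hdc and Tpsb2, had both genes lower, also adjusted over the list alone (median -1.56, adjusted p = 0.0224, and adjusted p = 0.165 with an estimated correlation); Hdc had itself risen with LPS in NS cells (5.37). Glycolysis genes were higher in 15 of 20 and lower in none (17 and none adjusted over the list alone, median 0.35, adjusted p = 2.94e-07, and adjusted p = 0.157 with an estimated correlation), with Hk3 at 0.99. Cell cycle arrest and p53 target genes were higher in 13 of 20 and lower in 1, the same adjusted over the list alone (median 0.51, adjusted p = 0.000213, and adjusted p = 0.0757 with an estimated correlation), with Trp53inp1 at 2.44 and a median of 0.309 after normexp correction.

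Cell cycle genes had a lower salt effect with LPS in 28 of 34 and a higher effect in 2 (30 and 2 adjusted over the list alone, median -0.45, adjusted p = 2.93e-08, and adjusted p = 0.400 with an estimated correlation), with Mki67 at -0.90. Ribosome biogenesis genes were lower in 11 of 26 and higher in none (13 and none adjusted over the list alone, median -0.21, adjusted p = 0.000128, and adjusted p = 0.438 with an estimated correlation), with Nop58 at -0.79. Lipid handling genes were higher in 13 of 25 and lower in 2 (15 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.00218, and adjusted p = 0.438 with an estimated correlation), with Abcg1 at 1.31, and immediate early genes were higher in 9 of 21 and lower in 2 (10 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.0270, and adjusted p = 0.438 with an estimated correlation), a call that ended with normexp correction (adjusted p = 0.122, median 0.154), with cyclic loess (0.0604) and without HS + LPS replicate 1 (0.0576). Osmolyte genes were higher in 7 of 14 and lower in none, the same adjusted over the list alone (median 0.43, adjusted p = 0.0104, and adjusted p = 0.497 with an estimated correlation), with Aqp1 at 1.69 and Hspa4l at 1.51. Antigen presentation genes were higher in 9 of 18 and lower in 2, the same adjusted over the list alone (median 0.21, adjusted p = 0.00736, and adjusted p = 0.497 with an estimated correlation), with the class II genes H2-Ab1 at 1.11 and H2-DMa at 0.74; normexp correction gave adjusted p = 0.0829.

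The 17 lists not called (adjusted p from 0.0804 to 0.961) had 73 higher and 77 lower of 384 genes, or 76 and 75 adjusted over the list alone. For immune functions the counts were 15 and 7 of 40 interferon-stimulated genes, 5 and 7 of 19 cytokines, 4 and 5 of 13 chemokines, 3 and 6 of 20 NF-kB regulators, 5 and 6 of 21 antimicrobial effectors, 5 and 1 of 11 alternative activation genes and 6 and 8 of 26 identity genes. The difference in the interferon-stimulated list between the settings was thus not shown (adjusted p = 0.0804). For the rest they were 4 and 2 of 18 ion transporters, 0 and 6 of 38 for oxidative phosphorylation, 5 and 1 of 22 for the TCA cycle, 5 and 4 of 23 for cholesterol synthesis, 5 and 7 of 29 for the integrated stress response, 2 and 7 of 21 for the unfolded protein response, 0 and 3 of 14 for heat shock, 5 and 4 of 26 for NRF2, 0 and 1 of 30 for ribosomal proteins and 4 and 2 of 13 for matrix genes. The median and mean differed in sign for the ion transporter, chemokine, antimicrobial and NRF2 lists. The other 8 marker lists, 27 genes, held 1 higher and 3 lower (1 and 7 adjusted over the list alone), with adjusted p from 0.305 to 0.989.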

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

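The tests with cyclic loess, the test on bright unnamed probes and the test weighted by brightness were chosen only after the results they measure were seen; the rule for bright unnamed probes was also changed then, by adding a margin for counting error. The salt effect differed between cells with and without LPS for 5013 of 13800 genes and for 12 of 37 lists, by the test of the interaction, though for none of the lists with an estimated correlation. All of these values include the HS + LPS arrays, which were alone on a slide and a scan day. Among 100 drawn regroupings of the salt labels within each LPS level, 1, the real one, gave as many genes, and the highest other gave 4455. That share was meant to exclude chance, but mixing the salt labels puts the salt effect into the residual spread. The draw therefore asks whether there was any salt effect, and it excludes nothing about a difference between the salt effects. The high others kept or exchanged all labels of the LPS arrays while mixing those without LPS, so they hold the salt effect with LPS whole and reflect a structure of the samples. For the other counts the real split was 1 of 10, too few for a share under 0.05. The real and highest other counts were 5116 and 0 for salt without LPS, 7933 and 2 for salt with LPS, 8793 and 0 for LPS without salt, and 9974 and 0 for LPS with salt.

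HIF-1 (median interaction 0.80), glycolysis (0.35), autophagy (0.26) and cell cycle arrest or p53 target genes (0.51) had a higher salt effect with LPS, and cell cycle genes (-0.45) a lower effect. Leading genes were Bnip3 1.72, Ddit4 1.61 and Egln3 1.41, Hk3 0.99, Pfkl 0.98 and Pfkfb3 0.97, Wipi1 1.31 and Ulk1 0.85, Trp53inp1 2.44, Phlda3 1.26, Sesn1 1.21 and Ccng1 1.20, and Mki67 -0.90, Cdk1 -0.88 and Cdc6 -0.80. An intensity trend between the dimmer HS + LPS arrays and the rest is argued against. At least 93.1% of each list's median stayed with cyclic loess. Of the 130 members, 128 were well above background on all 12 arrays, where the highest adjusted p was 0.000133. Members that were not detected thus do not account for the pattern. That test kept nearly all members, so it cannot exclude an effect of background on their values. With normexp correction the calls of the 5 lists held, but the arrest and p53 median fell from 0.51 to 0.309. Cdk1 went from -0.88 to -0.31 and lost its call. An effect of background on the size of the differences stays open. Slide and scan day cannot be told apart from the treatment: the NS + LPS array on its own slide differed from those on the shared slide by at most 0.045 over the 5 lists, but no other group shared the HS + LPS slide. A joint answer to salt and LPS may therefore explain the pattern, as may the slide, the scan day or the handling of that set of cultures, and none of the 5 lists passed with an estimated correlation (adjusted p = 0.0757 to 0.400).

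Interferon-stimulated genes were lower with salt in cells without LPS (median -0.40, 32 of 40 lower), a comparison within a slide, but not with an estimated correlation (adjusted p = 0.138). The median was -0.431 with cyclic loess (adjusted p = 2.99e-11), so an intensity trend does not account for it. Among the 36 members bright on all 6 arrays it was -0.387 with 29 lower, which argues against dim probes, and without each array in turn it lay between -0.436 and -0.381 (highest adjusted p = 7.94e-11), which argues against a single deviating array. A lower resting interferon tone with added NaCl is a possible explanation; a difference between the cultures of the groups was not tested and stays open.

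Probes without a gene symbol, which the comparisons leave out, were called in numbers of 1024 for salt without LPS, 3260 for salt with LPS, 2680 for LPS without salt, 4777 for LPS with salt and 1644 for the interaction, of 8299. With salt in LPS-treated cells 2247 were lower and 1013 higher, 2.22 lower for each higher. The ratio was 0.552 for salt without LPS, a lean upward (660 higher and 364 lower), and 1.19 for LPS without salt. It was 2.68 for LPS with salt and 4.22 for the interaction, so the strong downward leans lay in the comparisons that hold the HS + LPS arrays. Over probes bright on all 12 arrays, 829 were higher and 375 lower for salt without LPS. That upward lean adds to the ratio of the interaction. Cyclic loess took the ratio for salt with LPS to 1.06, but it centres the differences at each intensity, so that value decides nothing. Probes with a gene symbol, weighted to the same brightness, had 1.39 lower for each higher (counting error 0.0364), against 2.15 for the unnamed probes in the same fit. Being under the limit of 1.5, this argues against an intensity-dependent difference of the dimmer HS + LPS arrays as the whole cause, if both kinds of probe answer salt alike, which was not tested. Such a difference stays open as a part. Over probes bright on all 12 arrays the ratio for salt with LPS was 1.59. That is too near the limit of 1.5 for counting error to exclude dim probes as a part. The filter also drops probes that fell to background in HS + LPS, so it can lower the ratio whatever the cause. Over the same probes the ratio was 1.16 for LPS without salt, 2.16 for LPS with salt and 3.5 for the interaction. No biological explanation was tested.

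The other differences are given without weighing. By list, the median interactions were 0.43 for osmolyte genes, 0.21 for antigen presentation, 0.24 for osteoclast genes, 0.26 for lipid handling, -0.21 for ribosome biogenesis, 0.24 for immediate early genes and -1.56 for the mast cell markers. Osmolyte genes with a higher salt effect under LPS were Aqp1 1.69, Hspa4l 1.51, Akr1b3 1.23, Slc6a12 0.59 and Slc6a6 0.47. Immune genes went both ways, with Nos2 2.48, Gdf15 2.78, H2-Ab1 1.11, H2-DMa 0.74, Acp5 1.77 and Tnf 0.26 higher, and Il6 -3.72, Il1b -2.62, Ccl2 -2.52, Lcn2 -2.32, Clec7a -1.78 and Cxcl10 -1.28 lower. The values of Il6 and Il1b rest on groups without LPS in which they were not well above background on any array, so their size is not known. The rest were Lyzl4 4.24, Atp9a 2.99, Myom1 2.72, Gfi1 2.69, Epha2 2.60, Abcg1 1.31, Alox5 1.01, Nop58 -0.79, Upp1 -2.06 and Hdc -2.61. The call for Atp9a ended with the mean of its probes (0.53), and that for Cdk1 with normexp correction (-0.31).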

How the results depend on the processing

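Of the alternatives, cyclic loess was chosen only after the data were seen. The 5 counts of called genes stayed within a factor of 1.5 under every alternative that gave a value. Leaving out an array gave 3874 to 4740 genes for salt without LPS, 7066 to 7486 for salt with LPS, 8136 to 8502 for LPS without salt, 9493 to 9617 for LPS with salt and 4149 to 4766 for the interaction. The correlation of the salt effects ranged from 0.294 (no filter) to 0.545 (normexp correction). With a block for replicate number, whose numbers did not pair the arrays, the counts were 4689, 7584, 8604, 9800 and 4599. With an estimated correlation the called lists fell from 11, 10, 12, 19 and 12 to 0, 0, 5, 7 and 0 in the order above. With that estimate, 4, 4, 9, 10 and 6 of 37 lists had an unadjusted camera p under 0.05. The estimate was above the preset of 0.01 in all lists called for salt without LPS, such as osmolyte (0.34) and interferon-stimulated genes (0.093). In simulated genes without correlation, the camera p of the shifted list also rose, from 2.83e-28 to 2.07e-06. How much each adds to the fall was not tested. LPS without salt reversed for Dnaja1 with the mean of its probes (-0.225 against 0.47) and for Wipi2 within the shared slide (-0.51 against 1.20). The shared-slide fit chose each gene's brightest probe anew over its own arrays. A fixed slide block, which kept the probes of the main fit, reversed no gene result. A change of probe rather than the slide may thus account for Wipi2, and which probe was chosen is not reported here. Normexp correction ended calls for 36 of 721 gene results, no filter on dim probes for 35 and quantile normalization for 33. Fixed slide blocks and the shared slide alone gave no value for contrasts with HS + LPS, and camera was not run under the random slide block. Signal over background limits the dimmer HS + LPS arrays most.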

Other observations

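The tests of symbol families, of probe similarity and of probes downstream of genes were chosen only after the data were seen, and the marker lists before. Genes were also grouped by the root of their symbol, the letters before its first digit. The roots Ifi, Rps and Rpl share members with the lists. With salt in LPS-treated cells, 14 of 17 genes with the root Ifi, which leaves out Ifit genes, were lower (median -0.52). The camera adjusted p was 0.0013 over 78 symbol roots, but 0.942 with an estimated correlation, as for the other 3 roots called here. Of 48 Rps and 50 Rpl genes, 26 and 23 were higher (0.14 and 0.16; with quantile normalization the ribosomal protein list had a median of 0.0090 and no call). Of 77 olfactory receptor genes, Olfr, 38 were lower (-0.59), but 22 of the 77 were well above background on all arrays and the call ended with cyclic loess (-0.33, adjusted p = 0.235). The interaction called 8 roots, none of them with an estimated correlation (adjusted p from 0.751 to 0.826). Lower were 21 of 49 Mrpl (median -0.15; adjusted p = 0.00293), 26 of 77 Olfr (-0.60; 0.00293; with cyclic loess -0.29 and 0.0354), 8 of 29 Mrps (-0.18), 11 of 20 Nup (-0.31), 8 of 21 Taf (-0.20) and 6 of 15 Timm (-0.19; adjusted p = 0.041 for these 4) and 8 of 17 Vmn (-0.51; 0.0476), and higher were 12 of 28 Tbc (0.19; 0.0476). The calls of Vmn and Tbc ended with cyclic loess (adjusted p = 0.0826 for both; medians -0.29 and 0.23). No root passed with an estimated correlation. Salt without LPS called 3 roots, Ifi, Rpl and Rps, and LPS called 1, Ifi, both without and with added salt.

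Genes of immunoglobulin-like receptors were not tested as a set. Their values with salt, without and with LPS, were -2.85 and -2.87 for Pira2, -2.83 and -2.75 for Pira11, -2.25 and -2.51 for Pirb, 0.18 and 0.37 for Lilrb3 and -1.29 and -0.068 for Lilrb4a. Defensin genes were not tested as a set either, and the values were 2.68 and 2.38 for Defa-rs4 and 2.63 and 2.17 for Defa-rs2. Pirb, Lilrb3 and Lilrb4a were chosen after their values were seen. The probes of the receptor genes matched each other in at most 25 of 60 bases. Those of the defensins matched in up to 54, so several defensin probes do not measure separate genes with certainty. The probes of Defa-rs4 and Defa-rs2 were less alike, with 31 and 22 bases matching the closest defensin probe. Whether each probe binds transcripts of its relatives was not tested, nor whether the symbols Pirb and Lilrb3 stand for separate genes. Among unnamed probes well above background on all 6 arrays, the one that rose most with salt without LPS lies on chromosome 11, 107206058 to 107206117 (log2 difference 3.79, SE 0.18), and it also rose with LPS present (2.97). The probe at chromosome 1, 175814379 to 175814438, fell in both (-1.70 and -2.11).

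The markers of other cell types were measured as a check on foreign RNA. For salt without LPS, the higher and lower counts were 0 and 1 of 4 fibroblast genes, 0 and 0 of 4 epithelial, 1 and 1 of 3 endothelial, 1 and 0 of 4 T or NK cell, 0 and 1 of 3 B cell, 1 and 1 of 3 neutrophil, 0 and 1 of 2 dendritic, 1 and 0 of 2 mast cell and 1 and 0 of 4 erythroid genes. For salt with LPS, where slide and scan day differ, they were 0 and 2, 0 and 3, 1 and 0, 2 and 1, 0 and 0, 0 and 1, 0 and 1, 0 and 2, and 1 and 2 in the same order, so 12 of 29 genes were lower and 4 higher.

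Osmotic stress may let transcription run past gene ends, which would raise unnamed probes downstream of a gene on its strand. The test compared 1002 unnamed probes within 10 kb downstream of a gene's probe, on its strand, with 550 within that distance on the other strand, by 10000 permutations. Distance was taken from the gene's probe and not from its annotated end, so some of these probes may lie within the gene. The medians differed by -0.0070 without LPS (upper 95% bound 0.027, permutation p = 0.705) and by 0.085 with LPS (upper bound 0.152, permutation p = 0.0017). The hypothesis asked for over 0.1 in both. The bounds came from a bootstrap over probes. Both it and the permutations treat probes of the same arrays as independent, so neither measures the spread between samples. The value that decides was changed from the larger to the smaller difference after both were seen. Both differences lay under 0.1, but the upper bound did so only without LPS. The values without LPS show no shift of that size for probes downstream of a gene's probe, but they cannot decide on transcription past gene ends. With LPS the bound leaves a shift of that size open, and slide and scan day cannot be told apart from salt there.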
